A study of Homo sapiens with 4 samples.

How the data were processed

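The data are 10x Genomics single-cell libraries of sorted stromal vascular cells from human adipose tissue. Per the labels' protocols, whole tissue was frozen in CellSTOR reagent, thawed and digested with collagenase, red cells were lysed, and live cells were sorted on CD45 with an antibody to the red cell protein CD235a in the panel. The labels give 4 groups, omental or subcutaneous tissue with or without metabolic disease, and 1 library for each. They state 10 patients, 5 per cohort, with paired depots, but the files carry no donor label per cell, so neither pairs nor replicates could be formed.

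Each deposited matrix holds raw UMI counts per gene and barcode, whole numbers that the authors made with Cell Ranger 4, per the file headers. The genome build was hg38, per the submitters' processing notes. Each file lists 36601 genes and every barcode, so empty droplets are included, and no normalisation had been applied. The deposited counts were used as they are. Coordinates come from GENCODE 44 on hg38, matched by gene identifier. Aligner settings and the intended cell calling are not stated.

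Barcodes were called cells at 500 or more UMIs, 300 or more genes and at most 20% mitochondrial UMIs. Doublets were called per library with Scrublet (scanpy 1.11.5), with an expected rate of 0.008 per 1000 cells, and removed; they were 0.281%, 1.52%, 4.18% and 5.34% of cells in the libraries labelled omental without and with, and subcutaneous without and with, metabolic disease. UMIs in passing cells were 89.4%, 89.9%, 83.7% and 91.4% of each total. Cells of all libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with Leiden at resolution 1 (leidenalg 0.10.2). XIST, Y-linked, HLA, immunoglobulin and T cell receptor genes were kept out, and 120 XIST, TSIX and Y-linked genes were left out of all tables.

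Clusters were named from marker lists fixed before the data were examined. The thresholds for a name were set after seeing the clusters. A detected marker had 20 or more CPM and 2 times the median of the other clusters, a name needed 3 detected markers, and a cluster with a second class scoring above 0.5 times the first stayed unnamed. Classes of 500 or more cells were clustered again at resolution 0.8 on 20 components. Sub-clusters whose 10 leading genes held 3 or more markers of another class, and more than of their own, were set aside as mixed. Plasma cell genes did not count in this step, so sub-clusters led by immunoglobulin genes stayed in their class. Whether these transcripts are free RNA was not tested. Among named clusters, IGHG4 was a leading gene of mesothelial cluster 30 and CSF3 of endothelial cluster 13. No named cluster held more markers of another class than of its own among its 10 leading genes.

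Counts were summed per library and class and scaled to the class total (CPM). Classes with 50 or more cells in both libraries were compared, over genes with 50 or more counts in both together. With 1 library per group no test was made. Ratios carry the exact conditional 95% interval of the counts, CPM the exact Poisson interval and shares the exact binomial (Clopper-Pearson) interval, and all cover counting error only, not differences between patients or sorts. In endothelial cells labelled omental, CH25H with 313 against 3 counts had an interval of 1.62 to 5.47, while FAM118A in progenitors, with 1888 against 169 counts, had 2.35 to 2.81. A count of 0 was set to 3 counts, which makes the ratio a bound. Genes were named by a fixed rule. It took the 4 genes furthest above and the 4 furthest below (2 each in classes outside the 3 largest) by the interval limit nearest to 0, among genes with 50 or more counts and 20 or more CPM in the higher library. There they had to reach 0.5 times the level of the ambient profile and 0.1 times that of any class. Markers of other classes, HLA, KIR, immune receptor, mitochondrial and ribosomal protein genes and genes with no symbol of their own were left out. The text leaves out 2 of the genes that this rule takes. Members of a gene list are named by the largest absolute ratios, up to 4.

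For 29 gene lists fixed before the data were examined, the median log2 ratio was set against 10000 random lists matched in 10 bins of mean expression, and its interval comes from 200 Poisson resamples. Of 122, 198, 129 and 128 list summaries in the disease comparisons labelled omental and subcutaneous and the depot comparisons without and with disease, 58, 81, 65 and 71 lay outside percentiles 2.5 to 97.5. By the percentiles alone 6.1, 9.9, 6.45 and 6.4 would be expected there. The random lists draw genes independently, so lists of genes that vary together reach extreme percentiles more readily. An extreme percentile thus sets a list little apart. The lists reported were picked from those outside. The interferon and resident macrophage lists in myeloid cells and the cytotoxicity list in T or NK-like cells lay inside in 1 depot comparison each, and are given there beside the other cohort. The intervals were tested for each comparison on counts simulated from the Poisson model that they assume, without variation between cells. In progenitor cells of the disease comparison labelled omental they held the true ratio for 95.6% of 13074 genes. In the comparison labelled subcutaneous they did so for 95.5% of 13615 genes.

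Ambient profiles came from barcodes of 1 to 50 UMIs. From progenitor genes in T or NK-like cells, contamination was estimated at 1.16% and 1.47% of UMIs in the libraries labelled omental and 3.59% and 3.45% in those labelled subcutaneous. Alternatives tried were 1000 UMIs, 10% mitochondrial UMIs, a UMI minimum set per library, doublets kept, resolution 2, each library clustered alone, edgeR 4.0.16 TMM and DESeq2 1.42.0 median-of-ratios factors (R 4.3.3), the mean over cells of each cell's CPM, ambient subtraction, thinning to 500 UMIs per cell, and other count minimums. Ambient profiles of barcodes up to 100 UMIs and medians without single groups of sub-clusters were added after seeing the data. Work ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.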

Results

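Stromal vascular cells, which are the cells other than fat cells that collagenase digestion frees from adipose tissue, were profiled by droplet single-cell RNA sequencing (10x Genomics). Per the labels, the tissue came from the omentum, a fat depot inside the abdominal cavity, and from abdominal subcutaneous fat of 10 obese patients, 5 with and 5 without metabolic disease. The deposited files held 4 libraries, 1 for each depot and cohort, and no map from cells to patients. Every group was therefore 1 library that pools patients, and no difference below has a replicate check. Intervals are 95% intervals that cover counting error only.

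The library labelled omental without metabolic disease held 29453186 UMIs (unique molecular identifiers, each standing for 1 captured transcript) on 589164 listed barcodes. The library labelled omental with metabolic disease held 61326634 UMIs on 1284067 barcodes. The library labelled subcutaneous without metabolic disease held 121389640 UMIs on 1736750 barcodes, and the one with metabolic disease held 136407092 UMIs on 1768732 barcodes. In the same order, 3202, 6518, 17756 and 13512 barcodes passed as cells. After doublets were removed, 3193, 6419, 17013 and 12791 cells remained, with medians of 7162, 7367, 4414 and 7006 UMIs per cell. The labels state that up to 5000 cells per patient sample were sorted. Barcodes with 500 or more UMIs and 300 or more genes failed the 20% mitochondrial limit in 9.90%, 10.5%, 21.3% and 9.34% of cases.

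Cell classes were named from marker genes, and a class name below means a group of clusters that resembles that type. Of the cells kept, 14048 were progenitor or fibroblast-like, 10776 T or NK-like, 4914 mesothelial-like, 3298 myeloid-like, 1405 endothelial-like and 1051 mural-like (cells of vessel walls). B cell-like, plasma cell-like and plasmacytoid dendritic-like cells numbered 448, 202 and 176. Unnamed cells made up 1.10%, 1.03%, 7.56% and 3.78% of the libraries in the order above, and cells of mixed sub-clusters 0.814%, 1.60%, 3.43% and 4.02%. The labels describe a sort on CD45, an immune cell surface protein, that mixed positive and negative cells 50:50. Immune shares therefore follow the sort, and shares are given within immune and within stromal cells.

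Mesothelial-like cells, the lining cells of the abdominal cavity, lay in the libraries labelled subcutaneous. They made up 24.9% (exact binomial interval 23.9% to 25.8%) of 8058 stromal cells in the library without and 43.9% (42.7% to 45.1%) of 6625 in the library with metabolic disease. At a mitochondrial limit of 10% these shares were 12.1% and 30.4%. In the libraries labelled omental they were 0 of 2106 stromal cells (0% to 0.175%) and 2 of 4629, or 0.0432% (0.00523% to 0.156%). Genes of limb and trunk patterning were higher in progenitors of the libraries labelled omental, as given below. These cells and genes thus lay opposite to what the labelled depot would give in 4 of 4 libraries. Each library is called by its label throughout, and every depot direction below is that of the labels.

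**Figure D1:**
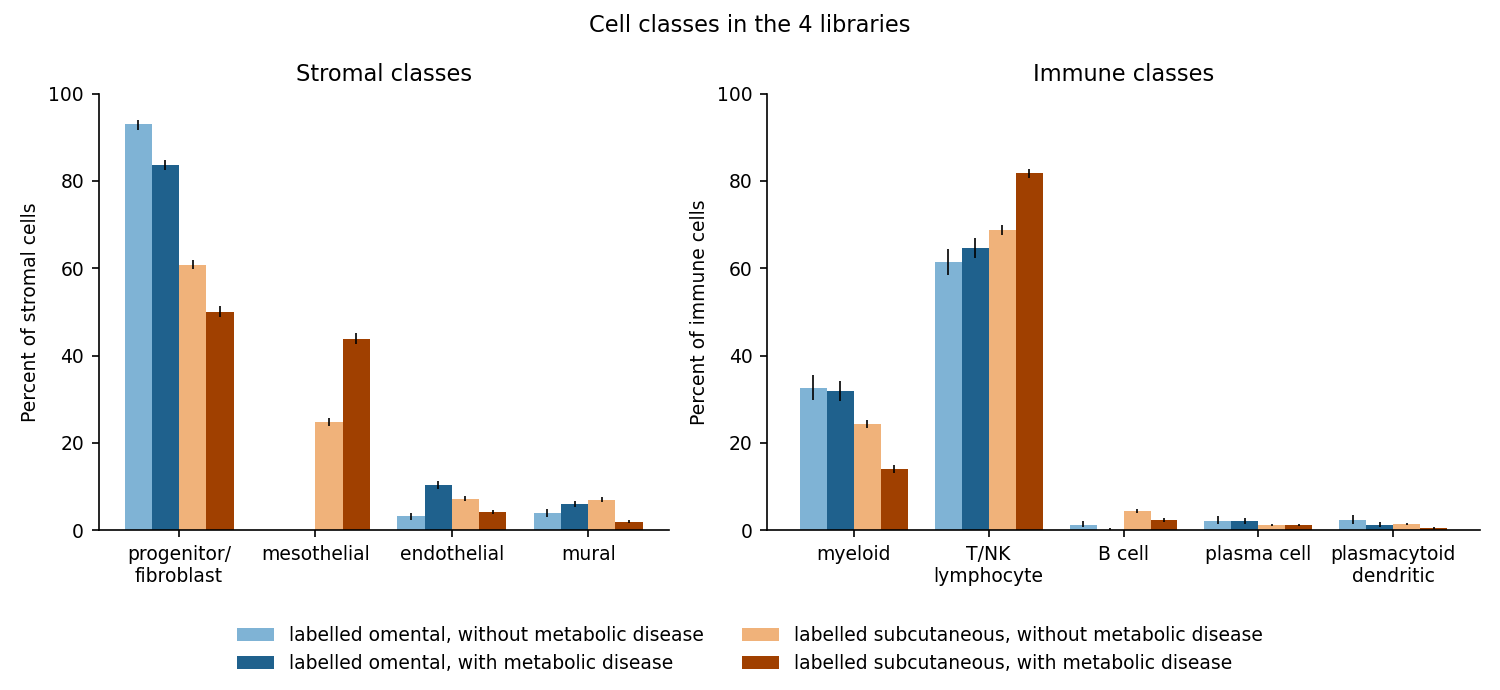
Shares of the cell classes (percent of stromal cells on the left, of immune cells on the right) in the 4 libraries, 1 bar per library with the exact 95% binomial interval as error bar. Mesothelial-like cells reach 24.9% and 43.9% of stromal cells in the libraries labelled subcutaneous and at most 0.0432% in those labelled omental.

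Progenitor-like cells made up 92.9% and 83.6% of stromal cells in the libraries labelled omental without and with metabolic disease, and 60.8% and 50.1% in those labelled subcutaneous. Endothelial-like cells made up 3.18% (2.47% to 4.02%) and 10.3% (9.42% to 11.2%) in the libraries labelled omental, and 7.28% (6.73% to 7.87%) and 4.15% (3.68% to 4.66%) in those labelled subcutaneous, again without and with metabolic disease. The share was thus higher with disease under the omental label and lower with disease under the subcutaneous label. Mural-like cells behaved alike, at 3.89% and 6.03% under the omental and 7.00% and 1.90% under the subcutaneous label, the latter 4.63% and 1.16% at a mitochondrial limit of 10%. These shares move with the mesothelial share, since all are parts of the same total.

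Among immune cells, T or NK-like cells made up 61.5% and 64.7% in the libraries labelled omental without and with metabolic disease and 68.8% and 81.8% in those labelled subcutaneous. The share in the library labelled omental with disease depended on the clustering. With each library clustered alone it was 39.1%, against 65.6% without disease, so that its direction with disease turned, and plasma cell-like cells there rose from 2.04% to 24.1%. Myeloid-like cells made up 32.7% (29.8% to 35.6%) and 31.8% (29.6% to 34.2%) under the omental label, which is no difference beyond counting error. Under the subcutaneous label they made up 24.3% (23.3% to 25.3%) and 14.0% (13.1% to 15%). Sub-clusters named from subtype markers fixed beforehand split the myeloid class. The resident macrophage markers are the same 13 genes as the resident macrophage list used below. Most lipid-associated macrophage markers belong to the lipid handling list. These shares and list medians are thus not independent. Lipid-associated macrophage-like cells were 12.2% (8.93% to 16.2%) of myeloid cells in the library labelled omental without and 24.0% (20.4% to 28.0%) in the one with metabolic disease. The libraries labelled subcutaneous held 0.813% and 2.62% of them. Monocyte-like cells were 62.4% (60.1% to 64.7%) of myeloid cells in the library labelled subcutaneous without and 29.8% (26.5% to 33.3%) in the one with metabolic disease. NK-like cells were 36.0% and 34.6% of T or NK-like cells under the omental label and 19.1% and 11.3% under the subcutaneous label. B cell-like cells were 4.33% (3.87% to 4.83%) and 2.42% (2.02% to 2.87%) of immune cells in the libraries labelled subcutaneous without and with metabolic disease.

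Ratios below compare CPM, which are UMI counts scaled to the class total, from counts summed over the cells of a class. A gene list's median log2 ratio is given with its percentile among 10000 random lists of equal size and matched expression. The median shift between libraries from TMM scaling exceeded 0.1 in some classes, and the ratios do not subtract it. It was 0.12 for myeloid cells in the disease comparison labelled omental, and -0.15 and -0.28 for B and plasma cells in the one labelled subcutaneous. In the depot comparison without disease it was -0.13 for myeloid, -0.14 for progenitor, -0.21 for endothelial and -0.11 for mural cells. In the depot comparison with disease it was 0.14 for T or NK, -0.11 for progenitor and -0.13 for endothelial cells. No direction stated below changed under TMM or median-of-ratios scaling. Thinning each cell to 500 UMIs left 48 of 168 ratios of named genes smaller by more than 1.5 times or turned. A gene that also leads a sub-cluster can differ because the share of that sub-cluster differs.

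The first comparison, with against without metabolic disease in the libraries labelled omental, asked how the cells of this depot differ with the disease. In myeloid cells (516 and 335), the lipid handling list had a median log2 ratio of 1.10 (1.05 to 1.16), at percentile 100, with 13 of 18 members at least 1.5-fold higher and 0 lower. Its largest members were SPP1 (ENSG00000118785, hg38 chromosome 4, 87975667 to 87983532) at 793 against 97.8 CPM, with a log2 ratio of 3.02 (2.86 to 3.18), APOE at 1106 against 256 CPM and 2.11 (2.01 to 2.21), GPNMB at 1.45 (1.25 to 1.65) and TREM2 at 1.42 (1.21 to 1.64). By the fixed rule, CHIT1 was the gene furthest above in the library with disease, at 126 against 3 counts and a log2 ratio of 4.62 (3.04 to 6.92), and RARRES1 had a ratio of 2.90 (2.12 to 3.81). When thinned these were 1.25 and 0.38. Without the lipid-associated macrophage-like sub-cluster the list's median was 0.51, as the mean of cells it was 0.64, and with cells thinned to 500 UMIs 0.39. The interferon response list lay higher too, at 0.81 (0.67 to 0.94, and 0.42 when thinned), and resident macrophage genes, 4 of 13 of them at least 1.5-fold higher, at 0.38 (0.32 to 0.47), which fell to 0.17 when thinned. The list of antigen presentation by class II proteins lay lower, at -0.38 (-0.40 to -0.17), with 0 of 9 members at least 1.5-fold higher or lower. It was -0.18 without the lipid-associated macrophage-like sub-cluster. Conventional dendritic-like cells were 44.5% (39.1% to 50.0%) of the class without and 26.2% (22.4% to 30.2%) with disease, and monocyte-like cells 12.8% and 22.3%. IDO1, DNASE1L3 and CCL22 were among the genes furthest below, with log2 ratios of -2.32, -1.71 and -1.56. These 3 are among the leading genes of myeloid cluster 25, which held 15.8% of myeloid cells without and 7.95% with disease.

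In T or NK-like cells of the same comparison (1048 and 631 cells), the metallothionein list had a median of -2.55 (-2.60 to -2.50), at percentile 0, with 5 of 7 members lower. MT2A stood at 1187 CPM with and 6970 CPM without disease, MT1X at 238 and 2249, MT1E at 136 and 1362, and MT1G at 21.4 and 397. Metallothionein genes are near-identical copies side by side on chromosome 16, so the split of reads among them is uncertain. Their sum was 1637 (1599 to 1675) CPM with and 11091 (10957 to 11226) CPM without disease. The cytotoxicity list lay at 0.38 (0.28 to 0.50), 6 of 19 members being at least 1.5-fold higher. It was 1.10 when NK-like sub-clusters were left out and 0.22 when thinned. CD8 T-like cells were 12.4% (9.89% to 15.2%) of the class without and 22.6% (20.1% to 25.3%) with disease. Cluster 18, with GZMH, NKG7 and CD8A among its leading genes, held 3.96% and 12.1%, so the list and CD8B may follow these shares. The genes furthest above were MYOM2 at 2.93 (2.52 to 3.37), MTRNR2L8, a nuclear copy of a mitochondrial gene whose reads are uncertain, at 1.69, IFNG at 1.57 (1.46 to 1.69) and CD8B at 1.58 (1.17 to 2.03). CGA had 0 counts with and 107 without disease and was at least 66.4-fold lower.

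Progenitor cells of the libraries labelled omental (3872 and 1957) had collagen genes lower with disease, with a list median of -0.49 (-0.54 to -0.45) at percentile 0 and 4 of 14 members at least 1.5-fold lower. The cells of the class lay in different sub-clusters. Progenitor sub-cluster 5, which THY1, POSTN and COL3A1 help to define, held 354 cells with and 818 without disease, and sub-cluster 2, led by APOC1 and PLA2G2A, 1576 and 238. The metallothionein list stood at -0.64 (-0.65 to -0.63). Inflammatory cytokines and chemokines were higher at 0.39 (0.24 to 0.42), with 8 of 19 measured members at least 1.5-fold higher and 4 lower, but at 0.16 after ambient subtraction. Visceral patterning genes stood at 0.57 (0.20 to 0.78), or 0.24 when thinned. The genes furthest above were FAM118A at 2.58 (2.35 to 2.81), COMP at 2.67 (2.32 to 3.04), LINC01436 at 2.66 (2.28 to 3.06) and DEPP1 at 2.15 (2.07 to 2.23). Those furthest below were MTRNR2L1, another uncertain nuclear copy, at -4.19, GNA11 at -1.54, PTGER2 at -1.45 and THY1 at -1.25 (-1.28 to -1.22). In endothelial cells, of which the library without disease held 67, the NF-kB response list lay at -0.40 (-0.70 to -0.32) and the inflammatory list at -0.43 (-0.72 to -0.39), or -0.80 after ambient subtraction and -1.30 with a minimum of 1 count. Inflammatory members went both ways: of 10 measured, 2 were at least 1.5-fold higher and 4 lower. CXCL3 and CXCL1 were furthest below there, at -3.20 and -3.26, and CH25H (313 against 3 counts) and CYGB furthest above, at 3.18 (1.62 to 5.47) and 2.40. The class changed its composition. Endothelial sub-cluster 2, which CXCL1 and CXCL3 help to define, held 11 of 476 cells with and 10 of 67 without disease, and sub-cluster 0, with CXCL10 and SELE, 195 and 11. Mural cells had an NF-kB median of -0.63 (-0.79 to -0.30), or -0.38 at a mitochondrial limit of 10%. CCL19 was furthest above in them, at 660 against 52.4 CPM, followed by PLCG2 at 3.02, and MTRNR2L1 (4 against 118 counts) and HSPA6 at -1.95 were furthest below. Mural sub-cluster 7, led by CCL19 and POSTN and with 2 progenitor but 0 mural markers among its leading genes, held 70 of 279 mural cells with and 10 of 82 without disease. Sub-cluster 6, led by HSPA6 and MTRNR2L1, held 34 and 24.

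The same question in the libraries labelled subcutaneous gave other leading genes. In T or NK-like cells (4226 with and 4871 without disease), the metallothionein list lay higher with disease, at 1.63 (1.62 to 1.76) and percentile 100. MT2A stood at 7964 CPM with and 2572 CPM without disease, and MT1E, MT1G and MT1X had log2 ratios of 2.10 (2.06 to 2.14), 2.03 (1.95 to 2.12) and 1.78 (1.76 to 1.81). A T or NK sub-cluster led by metallothionein genes held part of this signal, and the median was 0.66 without it. The cytotoxicity list lay lower with disease, at -0.42 (-0.49 to -0.31), with 6 of 19 members at least 1.5-fold lower. It was -0.12 without NK-like sub-clusters, whose share was 19.1% without and 11.3% with disease, and -0.27 without the sub-cluster led by metallothionein genes. IFIT2 at -2.95 (-3.14 to -2.77) and IFIT3 at -2.28 (-2.56 to -2.01) were the genes furthest below, before S1PR5 and LINC00299, both at -1.53. IFIT2 and IFIT3 help to define an NK-like sub-cluster of 91 cells with and 250 without disease. Metallothioneins were higher with disease in myeloid cells also, at 1.89 (1.80 to 1.95), or 2.86 after ambient subtraction, and in endothelial cells, at 1.40 (1.32 to 1.48), where MT1M and MT1E were furthest above and IL1RL1 (1 against 64 counts) and CCL8 furthest below, at -5.35 (-10.68 to -2.82) and -3.87 (-5.34 to -2.72). IL1RL1 was at -0.75 with doublets kept and 0.36 when thinned. The thinned value rests on at most 1 count in the library with disease, so its sign shows no reversal.

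**Figure D2:**
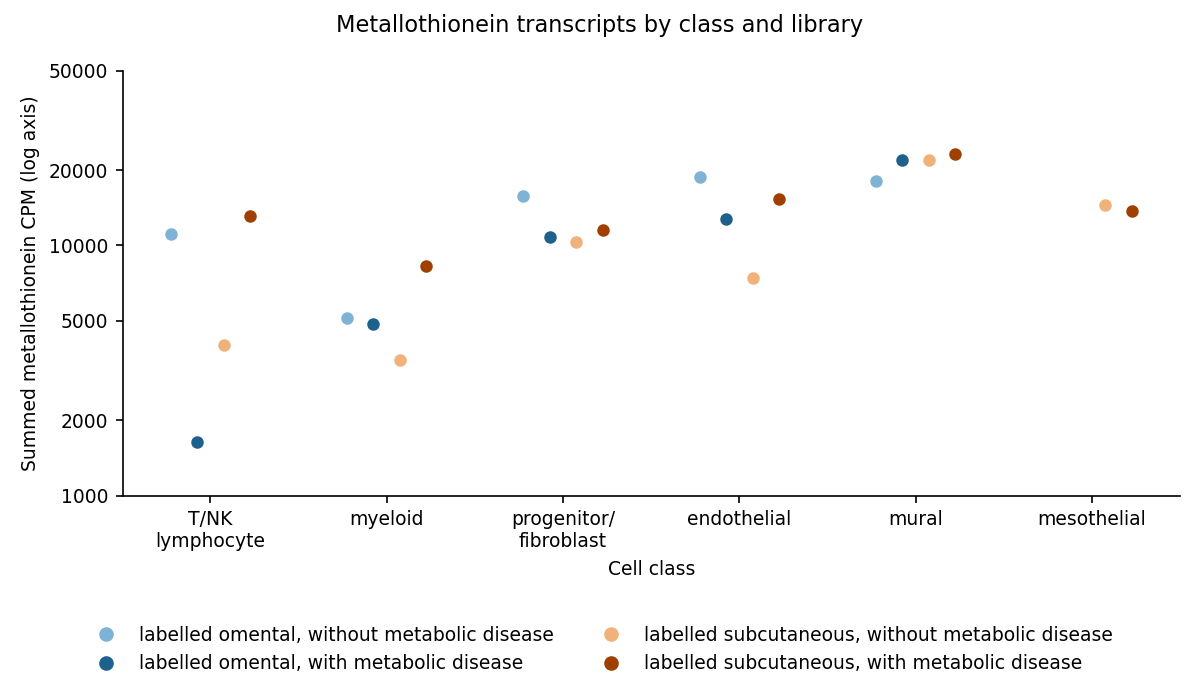
Summed CPM of the 7 metallothionein genes of the list (log axis) by cell class, 1 point per library, with exact 95% Poisson intervals that are narrower than most points. In T or NK-like cells the library labelled omental with metabolic disease lies at 1637 CPM and the one labelled subcutaneous with metabolic disease at 13096 CPM.

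Resident macrophage genes were higher with disease in myeloid cells labelled subcutaneous (724 and 1723), at 1.27 (1.24 to 1.38), with 13 of 13 members at least 1.5-fold higher. Without monocyte-like sub-clusters this median was 0.71. RNASE1, LYVE1, SELENOP and C1QB had log2 ratios of 1.93, 1.72, 1.62 and 1.58. The lipid handling list stood at 0.56 (0.48 to 0.64), with 9 of 18 members at least 1.5-fold higher. The class II list stood at 0.40 (0.37 to 0.45), with 0 of 9 members at least 1.5-fold higher and 1 lower, and became -0.023 without monocyte-like sub-clusters. MT1G at 3.38 and MT1X at 2.68 were furthest above, and CES1 at -2.34 and S100A9 at -1.61 furthest below. Cluster 12, led by S100A9 and S100A8, held 44.7% of these myeloid cells without and 19.1% with disease. Cluster 8, led by dendritic cell genes but with VSIG4 among its leading genes, held 24.3% and 44.8%. Resident macrophage-like sub-clusters held 19.1% (17.3% to 21.0%) of the class without and 39.9% (36.3% to 43.6%) with disease. The genes of the resident macrophage list named these sub-clusters, so this share does not add to the list median. The list was not recomputed without them. Conventional dendritic-like sub-clusters held 15.4% and 22.7%.

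Progenitors labelled subcutaneous (3316 with and 4903 without disease) had the DPP4 progenitor list higher with disease, at 1.08 (0.88 to 1.13), with 10 of 13 members at least 1.5-fold higher and 2 lower. PRG4 at 2.42, DPP4 at 1.70, MFAP5 at 1.56 and PI16 at 1.36 were its largest members. Cluster 11, which MFAP5 and PI16 help to define, held 15.1% of the progenitors with and 3.71% without disease. Heat shock genes lay at -0.56 (-0.59 to -0.53), inflammatory genes at -0.39 (-0.42 to -0.30), or -0.26 after ambient subtraction, collagens at -0.30 (-0.33 to -0.28), visceral patterning genes at -0.32 (-0.43 to -0.28) and metallothioneins at 0.43 (0.41 to 0.46). Of the members, 5 of 13 heat shock genes, 9 of 19 inflammatory genes, 3 of 14 collagens and 4 of 9 visceral patterning genes were at least 1.5-fold lower, and 3 of 7 metallothioneins were higher. The other way went 4 of the 19 inflammatory genes and 1 of the 7 metallothioneins. PLA2G2A was furthest above, at 881 (870 to 892) against 167 (162 to 172) CPM, before GALNT15, CYP4B1 and DKK1 at 2.33, 2.24 and 2.23. ADAMTS4, ZNF331, PGAP1 and CCL11 were furthest below, at -2.57, -2.40, -2.38 and -2.26. Progenitor sub-cluster 1, which ZNF331, CCL11 and PGAP1 help to define, held 61 cells with and 1770 without disease, and sub-cluster 8 held 52 and 614, so these ratios compare sub-clusters as much as libraries. In endothelial cells the inflammatory list lay at -0.68 (-0.92 to -0.38), with values from -1.28 after ambient subtraction to -0.15 when thinned, and in mural cells, of which the library with disease held 126, the heat shock list at -0.40 (-0.55 to -0.35), or -0.63 at a mitochondrial limit of 10%. HSPA6 at -1.68, or -4.47 at that limit, and STEAP4 at -1.90 were furthest below in mural cells. CCN3 at 2.25 (1.73 to 2.77) and CCN2 at 1.13 (0.92 to 1.33) were furthest above, but these became -1.18 and -0.17 at a mitochondrial limit of 10%. The NF-kB list lay at -0.74 (-0.92 to -0.55) in B cells (-0.46 with doublets kept) and -0.93 (-1.18 to -0.83) in plasma cells (-0.41 when thinned), of which the libraries with and without disease held 125 and 307, and 62 and 84. RNASE6 at 2.77 and VPREB3 at 1.49 were furthest above in B cells, and GEM (2 against 86 counts) and MTRNR2L8 at -2.29 furthest below. In plasma cells these were PLA2G2D at 2.58 and JSRP1 at 2.30, and FBXL22 (1 against 135 counts) and CCL3 at -6.83, a gene with near-identical copies. When thinned, GEM was -0.12 and FBXL22 0.023, and CCL3 was -2.87 as the mean of cells. The thinned FBXL22 value rests on at most 1 count in the library with disease, so its sign shows no reversal.

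Mesothelial-like cells could be compared only under the subcutaneous label (2908 with and 2004 without disease). Cluster 4, led by PCK1, HP and ITLN1, held 79.5% of them with disease, while cluster 5, led by KRT18, KRT8 and SERPINB2, held 89.3% of them without disease. A cluster mostly of 1 library may be that library rather than a cell state, and the values below compare these clusters as much as the libraries. The NF-kB response list was lower with disease, at -1.05 (-1.11 to -0.98), with 12 of 14 members at least 1.5-fold lower. RELB, NFKB2, NFKB1 and BIRC3 had log2 ratios of -1.31, -1.27, -1.20 and -1.19. The inflammatory list stood at -0.52 (-0.62 to -0.25), or -1.10 after ambient subtraction, and immediate early genes at 0.64 (0.63 to 0.65). CTAG2, a member of a family of near-identical genes, had 1660 counts with and 0 without disease and was at least 252-fold higher. TXNIP at 2.47 (2.43 to 2.52), PCK1 (ENSG00000124253, hg38 chromosome 20, 57561080 to 57568121) at 2.41 (2.31 to 2.52) and CHAC1 at 2.29 (2.01 to 2.57) followed. IL24 at -3.60, DUSP4 at -2.58, SERPINB2 at -2.46 and FOSL1 at -2.37 were furthest below. PCK1 leads cluster 4, and IL24 and SERPINB2 lead cluster 5.

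**Figure D3:**
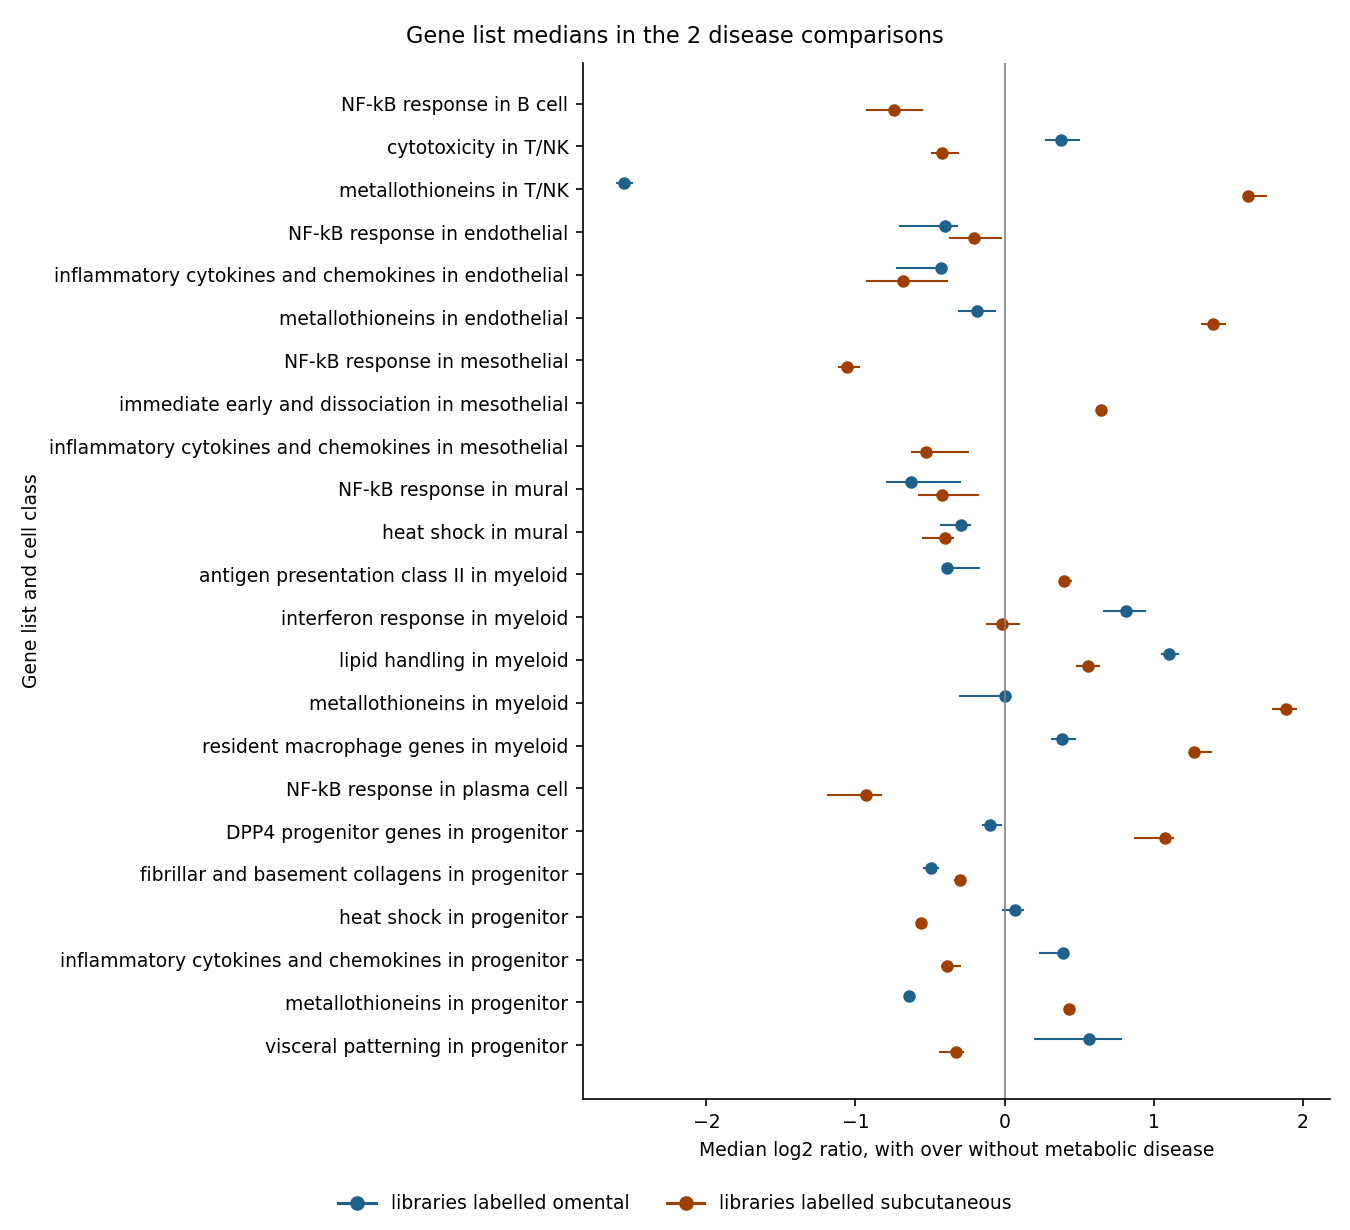
Median log2 ratio, with over without metabolic disease, of gene lists in cell classes, for the libraries labelled omental and those labelled subcutaneous, with lines for 95% intervals of counting error. Metallothioneins in T or NK-like cells lie at -2.55 under the omental and 1.63 under the subcutaneous label.

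The depot comparisons asked how cells of the omentum differ from those of subcutaneous fat, in each cohort. In progenitors the limb and trunk patterning list was higher in the library labelled omental, with a median log2 ratio of 5.35 (4.96 to 5.82) without disease and 3.97 (3.62 to 4.16) with disease. Thinned to 500 UMIs, the medians were 3.26 and 3.21. In each cohort 15 of 18 members were at least 1.5-fold higher and 2 lower. HOXC9 (ENSG00000180806, hg38 chromosome 12, 53994895 to 54003337) had 729 against 3 counts without disease, a log2 ratio of 8.45 (6.90 to 10.73), and 1434 against 22 counts with disease, a ratio of 5.71 (5.10 to 6.39). IRX2 stood at 8.31 (6.94 to 10.18) and 6.02 (5.43 to 6.68). The visceral patterning list lay lower, at -4.19 (-5.08 to -3.50), or -2.67 when thinned, and -1.79 (-2.31 to -1.71), or -2.79 with a minimum of 10 counts, with 9 of 9 measured members lower in both cohorts. WT1, which with BNC1 is also a mesothelial marker, stood at 0.160 against 70.1 CPM without disease and 0.257 against 38.4 CPM with disease. ISL1 had 0 against 252 counts without disease and 1 against 293 with disease, and NR2F1 and TCF21 had log2 ratios of -7.22 and -6.90 without disease. Different clusters held the progenitors: cluster 1 held 92.9% and 89.7% of those labelled omental, and clusters 0 and 6 held 72.4% and 23.1% of those labelled subcutaneous without disease and 56.7% and 26.4% with disease.

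**Figure D4:**
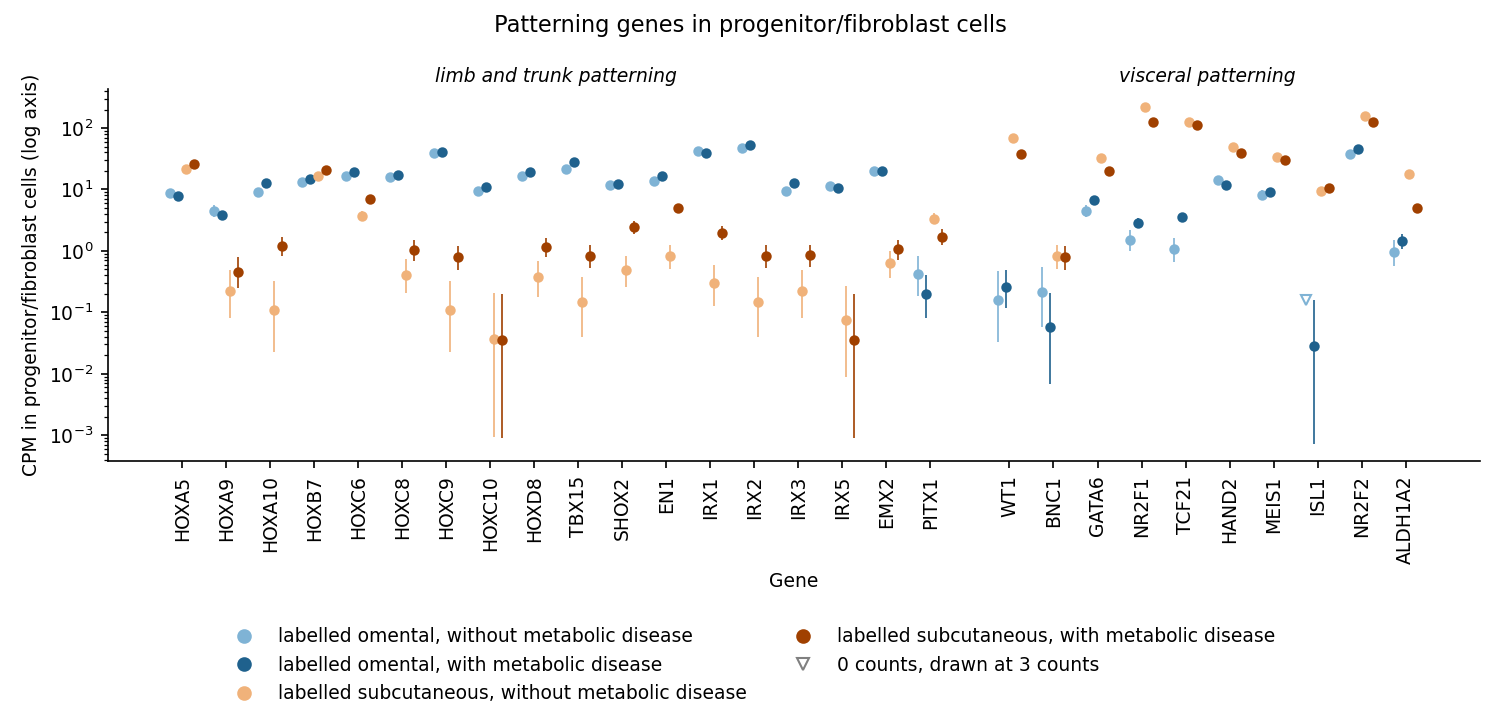
CPM of each patterning gene with 50 or more counts in progenitor-like cells (log axis), 1 point per library with its exact 95% Poisson interval, and an open triangle at 3 counts where a library had 0. HOXC9 stands at 38.9 and 40.9 CPM under the omental label and at 0.111 and 0.782 CPM under the subcutaneous label, while HOXA5 and PITX1 lie the other way.

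By the fixed rule, C5orf38 (525 against 0 counts, at least 252-fold higher), IRX2, HOXC9 and CRNDE were furthest above in progenitors labelled omental without disease, and NRN1, CRNDE, IRX2 and HOXC9 with disease. Furthest below were CCL11 (1 against 3007 counts), NFASC (0 against 926 counts, at least 214-fold lower), PTN at -7.22 (-7.50 to -6.96) and IGFBP2 at -7.52 (-8.18 to -6.93) without disease. With disease they were WIF1 (1 against 606 counts), BARX1 (5 against 976), the antisense gene WT1-AS, whose reads cannot be told apart from those of WT1 unless strand was used, and IGFBP2 at -5.96 (-6.21 to -5.72). CRNDE and THY1 lead cluster 1, PTN and CCL11 lead cluster 0, and IGFBP2 helps to define cluster 6. Collagen genes were higher under the omental label, at 0.54 (0.52 to 0.57), or 0.35 as the mean of cells, and 0.60 (0.58 to 0.61), as was the NF-kB list, at 0.82 (0.60 to 0.94) and 1.06 (0.99 to 1.14). The class II list was lower, at -1.02 (-1.54 to -0.62) and -1.79 (-1.94 to -1.65), the latter -3.68 after ambient subtraction.

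In myeloid cells the lipid handling list was higher under the omental label, at 1.44 (1.29 to 1.53) without and 1.73 (1.63 to 1.84) with disease. Without the lipid-associated macrophage-like sub-cluster, whose share differed between the depots, these medians were 0.59 and 0.46. FABP4 (ENSG00000170323, hg38 chromosome 8, 81478419 to 81483236) stood at 3262 against 102 CPM and 7197 against 400.4 CPM, and LPL had log2 ratios of 3.09 (2.70 to 3.50) and 2.82 (2.56 to 3.09). SPP1 was furthest above with disease, at 5.19 (4.97 to 5.43), and had a ratio of 2.18 (1.94 to 2.42) without disease, or 3.84 at a mitochondrial limit of 10%. CCL22 at 4.07 and MATK at 3.30 were among those furthest above without disease, and CHIT1 at 6.25 (4.37 to 9.31) and MMP7 at 3.48 with disease. The interferon response list lay at -0.92 (-1.08 to -0.80) without disease, or -0.54 when thinned, and at -0.12 (-0.26 to -0.05) with disease, the latter at percentile 28.8 and at -0.44 as the mean of cells. Resident macrophage genes lay at 0.10 (0.02 to 0.19) without disease, at percentile 84.6, and at -0.75 (-0.83 to -0.71) with disease. Without monocyte-like sub-clusters the former turned to -0.69 and the latter was -0.91, so the cohorts did not differ in direction there. FN1, S100A8, S100A9 and LINC02432 were furthest below without disease, at -4.32 (-6.76 after ambient subtraction), -3.22, -2.97 and -3.79, and CXCL9, LYPD2, MT1X and TTN with disease, at -3.89, -3.46, -2.13 and -2.42 (-4.11 at a mitochondrial limit of 10%). Monocyte-like cells were 12.8% of the class labelled omental and 62.4% of that labelled subcutaneous without disease, and 22.3% and 29.8% with disease. Myeloid sub-cluster 12, with FN1, CXCL9, ISG15 and IFIT3 among its leading genes, held 0 and 0 cells labelled omental and 21 and 21 labelled subcutaneous. Ratios of such genes and of the interferon list may follow these shares.

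In T or NK-like cells the metallothionein list lay at 1.44 (1.40 to 1.46) without and -2.75 (-2.78 to -2.71) with disease, so its depot direction differed between the cohorts. Without the sub-cluster led by metallothionein genes, which held 5 cells of the library labelled omental and 692 of the one labelled subcutaneous with disease, the latter median was -1.12. Cell cycle genes were higher under the omental label in both, at 0.77 (0.55 to 1.05) and 0.98 (0.81 to 1.14). Cluster 24 held 6.18% and 6.39% of the class under the omental label. Under the subcutaneous label it held 1.01% and 1.35%. Its leading genes were regulatory T cell genes such as CTLA4 and TNFRSF4 as well as the cell cycle genes TYMS, STMN1 and MKI67. The sub-cluster led by TYMS, with MKI67, was smaller. It held 9 of 631 and 17 of 1048 cells under the omental label, and 30 of 4871 and 19 of 4226 under the subcutaneous label. The cytotoxicity list lay at 0.16 (0.03 to 0.20), at percentile 95.5, and 1.02 (0.96 to 1.13), and the former became -0.41 without NK-like sub-clusters. CD177 was among the genes furthest above in both cohorts, at 3.35 (2.73 to 3.98) and 3.33 (2.85 to 3.82), with CGA (107 against 4 counts) without disease and MYOM2, LAIR2 and OSBPL5 at 3.25, 2.66 and 2.47 with disease. CD177 and CGA help to define the regulatory T-like sub-cluster, which held 4.91% and 4.87% of the class under the omental and 0.862% and 1.66% under the subcutaneous label. Metallothionein genes filled the other places, MT1G and MT1E above without disease and MT1G, MT1X, MT1E and MT2A below with disease. IFIT2, IL10, IL2 and RGPD5, a member of a family of near-identical genes, were furthest below without disease, at -3.33, -3.03 (-4.67 at a mitochondrial limit of 10%), -2.76 and -2.69.

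Endothelial cells labelled omental had the NF-kB list higher, at 1.26 (0.98 to 1.43) without and 0.85 (0.71 to 1.05) with disease, and the inflammatory list at 1.56 (1.40 to 1.66) and 1.92 (1.58 to 2.19). The inflammatory medians depended on the minimum count of a member. They were 0.29 and 0.51 with a minimum of 10 counts, and the value with disease turned to -0.62 with a minimum of 1 count. Without disease CXCL3 at 4.44 and CXCL1, which was 7.99-fold higher, were furthest above, and CCL21 at -6.65 (-8.28 to -5.43) and SPP1 (0 against 348 counts, at least 15.8-fold lower) furthest below. With disease TAC1 (175 against 0 counts, at least 23.8-fold higher) and CXCL10 (252 against 2) were furthest above, and TFF3 at -6.10 was among those furthest below. Thinned to 500 UMIs, SPP1 was 0.39 and TAC1 -0.055. The library with 0 counts was set to 3 counts there, a high CPM in so small a total. These signs thus show no reversal. The cells lay in different sub-clusters. With disease, sub-cluster 7, led by TAC1, held 99 of 476 cells labelled omental and 0 of 275 labelled subcutaneous, and sub-cluster 0, with CXCL10 and SELE, 195 and 4. CCL21 and TFF3 lead the lymphatic endothelial-like sub-cluster, which held 19.6% and 18.2% of endothelial cells under the subcutaneous label and 5.97% and 0.630% under the omental label. In mural cells the NF-kB list lay at 1.20 (1.00 to 1.38) and 1.29 (0.86 to 1.74), where the latter turned to -0.15 when thinned to 500 UMIs. Collagens lay at 1.23 (1.12 to 1.37), or 0.58 at a mitochondrial limit of 10%, and 1.05 (0.88 to 1.25). POSTN was higher under the omental label, at 5.60 (5.02 to 6.24) and 6.58 (4.72 to 9.63), as were MTRNR2L1 at 3.18 without and CCL19 (1216 against 3 counts) with disease. TCF21 (0 against 375 counts and 5 against 142) and BARX1 (1 against 467 and 0 against 96) were lower in both cohorts. Thinned, TCF21 was -0.72 and -2.88, BARX1 -0.80 and -2.15, and POSTN with disease 2.44. The ratios with a 0 count, TCF21 without and BARX1 with disease, are bounds. Sub-cluster 7, led by CCL19 and POSTN, held 10 and 70 mural cells under the omental but 18 of 564 and 1 of 126 under the subcutaneous label, and sub-cluster 4, led by CXCL1, held 28 and 89 but 5 and 0. These mural ratios thus compare sub-clusters as much as libraries.

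The disease comparisons share no library, so they can be set against each other, across genes that are not independent replicates. Per the labels the depots of a cohort came from the same patients, so both comparisons set the same patients against each other, and r includes fixed differences between patients. Pearson's r of their log2 ratios was 0.174 (0.161 to 0.188) over 12662 genes in progenitors, 0.177 (0.161 to 0.189) over 8504 in myeloid cells, 0.128 (0.105 to 0.146) over 7817 in T or NK-like cells, 0.153 in endothelial and 0.0438 in mural cells. Genes had the same sign in 52.0% of cases in progenitors, 59.3% in myeloid cells and 52.1% in T or NK-like cells. Over genes with 200 or more counts, r was 0.0835 in T or NK-like, 0.232 in endothelial and 0.0192 in mural cells. Of the 83 progenitor genes that differed 2-fold or more in both, 78.3% had the same sign, against 30.8% of 13 in T or NK-like cells. For the depot comparisons r was 0.816 (0.811 to 0.820) over 12978 genes in progenitors, 0.553 in myeloid, 0.499 in T or NK-like, 0.463 in endothelial and 0.506 in mural cells. Of the 1103 progenitor genes that differed 2-fold or more in both, 99.5% had the same sign. These are 10 correlations in all, and each interval comes from resampled counts.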

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

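The tests of mesothelial marker UMIs in all called cells, and of other classes' markers in the cells rich in them, were chosen only after the result was seen, as were the medians without single groups of sub-clusters and the reading of the corrected metallothionein medians. The other tests were written down before their result was seen.

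The results below moved in opposite directions with metabolic disease in the libraries labelled omental and those labelled subcutaneous. Each group is 1 library, so the difference itself was not tested. Per the labels both depots came from the same patients, so patient differences common to both depots cancel in it, while others, such as unequal cell numbers per patient, remain. Values are the log2 ratio under the subcutaneous label minus that under the omental label. In T or NK-like cells the metallothionein list differed by 4.18, MT1G by 6.24, MT1E by 5.42, MT1X by 5.02 and MT2A by 4.18, all lower with disease under the omental and higher under the subcutaneous label. CGA differed by 9.69, where the omental ratio is a bound. The cytotoxicity list differed by -0.80, higher with disease under the omental and lower under the subcutaneous label. In myeloid cells the class II antigen presentation list differed by 0.78, IDO1 by 3.43 and CCL22 by 3.97. In progenitors the metallothionein list differed by 1.07, the inflammatory list by -0.78, the visceral patterning list by -0.89, COMP by -3.96 and CCL11 by -8.11. The visceral list had 7 measured members under the omental and 9 under the subcutaneous label, so its medians cover unlike sets of genes. CCL11 had 1 count in the library labelled omental without disease.

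Part of this depends on single groups of sub-clusters. The cytotoxicity list in T or NK-like cells labelled subcutaneous was -0.12 without NK-like sub-clusters, and under the omental label 1.10. The subcutaneous side thus depends on NK-like cells, but whether on their share or on a change within them was not separated. Without the sub-cluster led by metallothionein genes that side was -0.27. On the omental side CD8 T-like cells were 12.4% of the class without and 22.6% with disease. The cytotoxicity list was not recomputed without them. The class II list in myeloid cells labelled subcutaneous fell from 0.40 to -0.023 when monocyte-like sub-clusters were left out, so its opposite direction may come from monocyte-like cells, by their share or a change within them. Under the omental label conventional dendritic-like cells were 44.5% of myeloid cells without and 26.2% with disease. The class II list was not recomputed without them. The metallothionein list in T or NK-like cells labelled subcutaneous stood at 0.66 without the sub-cluster led by these genes and kept its direction. Under the omental label it stood at -2.41 without that sub-cluster. The metallothionein medians labelled omental and subcutaneous were -2.66 and 1.70 after ambient subtraction, -2.52 and 1.70 thinned to 500 UMIs, and -2.57 and 1.96 at a mitochondrial limit of 10%. The same corrections moved lipid handling in myeloid cells labelled omental from 1.10 to 0.39 (thinned) and myeloid metallothioneins labelled subcutaneous from 1.89 to 2.86 (ambient subtracted). This argues against free RNA, depth or damage seen as mitochondrial UMIs as the whole cause. Handling was not tested, so the origin stays open.

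Mesothelial-like cells lay in the libraries labelled subcutaneous, where they were 24.9% and 43.9% of stromal cells. Free RNA or doublets from a few mesothelial cells were tested first. Mesothelial markers in these cells lay at a median of 5.38 times their ambient level in the library without and 3.05 times in the one with disease. The bound of 5 set beforehand was not met in the latter, so this test alone left the question open. Free RNA that reaches every cell alike was then tested on all called cells, whatever their class and with called doublets kept. Of these, 12.5% in the library without and 20.3% in the one with disease (lower limits 12.1% and 19.6%) passed a limit of mesothelial marker UMIs. A droplet of ambient RNA alone would pass it by chance at 0.001. Most of the cells above it, 1925 of 2227 and 2415 of 2744, were the mesothelial-like cells, which the same markers had named. The naming thus made this result likely, and it argues only against free RNA spread evenly over all cells. Doublets were tested in all cells above that limit by the markers of 5 other classes. Their median levels, as a percent of the level in each class, summed to 10.4% and 6.85% in the 2 libraries. Both sums lay below the 25 or more set for doublets as the cause. The bound of 10 or less in both libraries that would argue against doublets was not met in 1 of them, so this test left doublets open. Of the cells above the limit, 217 of 2227 and 252 of 2744 were called doublets.

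An exchange of the depot labels was tested on patterning genes of progenitors, a different class. Their limb and trunk list was higher under the omental label by a median log2 of at least 3.97 in both cohorts, and the visceral list lay at -1.79 or lower. An exchange could have been ruled out by this test and was not, and it needs all 4 libraries to be out of place, which is what was seen. The labels or the files may thus carry the depots exchanged. The same values would follow from an exchange at sampling, at loading or in the deposit, and the tables do not separate these. If the depots are exchanged within each cohort, each disease comparison stays whole but belongs to the other depot. An exchange of the disease labels was not tested, since no marker of them is known from the labels.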

How the results depend on the processing

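The medians without single groups of sub-clusters and the ambient profile of barcodes up to 100 UMIs were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the files hold 1 pooled library per depot and cohort, with no donor label per cell. There was no replicate to leave out, for the same reason.

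Of 741 alternative values of 63 list medians, 499 stayed within counting error, 237 moved beyond it (114 away from 0 and 123 towards 0) and 5 changed sign. Of 1536 values of 171 genes named by the rule or as list members, 1226 stayed, 304 moved (114 away from 0, 190 towards 0) and 6 changed sign. Of 232 values of 68 shares with 20 or more cells, 176 stayed and 56 moved, 25 up and 31 down. Of 30 values of 10 correlations, 20 stayed and 10 moved. The TMM value of each correlation could not move, since TMM shifts all ratios of a comparison alike, which leaves r unchanged. Thinned values were left out where both libraries had 3 counts or fewer, and subtype shares were recomputed only at 1000 UMIs and at 10% mitochondrial UMIs.

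At a limit of 10% mitochondrial UMIs, the libraries labelled subcutaneous without and with metabolic disease held 11723 and 8942 cells, and mesothelial shares of 12.1% and 30.4%. With each library clustered alone the share with disease was 38.0%. In mural cells CCN3 became -1.18 and CCN2 -0.17 at 10% mitochondrial UMIs.

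Lipid handling in myeloid cells labelled omental, with over without disease, stood at 0.98 with TMM, 0.98 with median of ratios, 0.64 as the mean of cells, 1.29 at 10% mitochondrial UMIs, 0.39 thinned to 500 UMIs, 1.21 without monocyte-like and 0.51 without lipid-associated macrophage-like sub-clusters. It kept its direction under every alternative run. Metallothioneins in T or NK-like cells labelled subcutaneous stood at 1.56 as the mean of cells, 1.61 with doublets kept, 1.96 at 10% mitochondrial UMIs, 1.62 without NK-like sub-clusters and 0.66 without the sub-cluster led by metallothionein genes, and kept their direction too.

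Limb and trunk patterning in progenitors, labelled omental over subcutaneous, stood at 3.26 without and 3.21 with disease when thinned to 500 UMIs, and at 4.24 with disease as the mean of cells. Over genes with 200 counts, r of the disease comparisons in progenitors was 0.151 and of the depot comparisons 0.826.

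These results changed sign. Without monocyte-like sub-clusters, class II genes in myeloid cells labelled subcutaneous became -0.023 and resident macrophage genes in the depot comparison without disease -0.69. Without NK-like sub-clusters, cytotoxicity in that comparison became -0.41. With a minimum of 1 count, endothelial inflammatory genes in the depot comparison with disease became -0.62. Thinned to 500 UMIs, the mural NF-kB list of that comparison became -0.15, endothelial TAC1 -0.055, endothelial SPP1 without disease 0.39, endothelial IL1RL1 labelled subcutaneous 0.36 and FBXL22 in plasma cells 0.023. Thinning leaves few counts in these small classes.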

Other observations

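The tests in this part were written down before their result was seen, except that the heat shock values were added after. Each pattern was noticed in these data, and any explanation of it is a hypothesis.

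Some types that also circulate in blood were more frequent in the library labelled subcutaneous without than in the one with metabolic disease. Monocyte-like cells were 62.4% and 29.8% of myeloid cells, and B cell-like cells 4.33% and 2.42% of immune cells. Plasmacytoid dendritic-like cells were 1.40% and 0.619% of immune cells, and NK-like cells 19.1% and 11.3% of T or NK-like cells. T or NK-like cells together, which circulate too, went the other way, with 68.8% and 81.8% of immune cells. More blood in that library was tested by haemoglobin in the ambient profile, which was 35.9-fold higher (11.9 to 177) in the library without disease, at 103 against 3 counts. Blood left in the tissue may thus have raised the shares that were higher there. The labels describe red cell lysis and a sort against CD235a, which would remove whole red cells but not free haemoglobin RNA, so the ratio may also follow the lysis of each batch of cells. HBA1 and HBA2 are near-identical copies and were summed with HBB. Ambient haemoglobin was 55.9 CPM in that library but 3.51 and 6.85 CPM in the libraries labelled omental without and with disease. There monocyte-like shares, at 12.8% and 22.3%, were lower too, but NK-like shares, at 36.0% and 34.6%, were higher. Across the 4 libraries the NK-like share thus did not follow haemoglobin, though the labelled depot differs as well. A difference in disease stays open, as do pools of different patients. Circulating T or NK-like cells cannot be separated from those of the tissue by these counts.

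Mesothelial-like cells were in different states in the libraries labelled subcutaneous. Cluster 5, led by KRT18, KRT8 and SERPINB2, held 89.3% of them without and 16.5% with disease. A difference in cell depth or damage was tested by holding both libraries to cells of 5000 to 20000 UMIs and at most 10% mitochondrial UMIs. The shares were then 89.3% of 507 cells and 14.3% of 869 cells, a difference of 75.1 points. This argues against UMI depth or mitochondrial share of single cells as the whole cause. The clusters were those of all cells, so damage common to every cell of a library could not be seen by this test. A dissociation response common to all cells of a library was tested by immediate early genes. Their median log2 ratio was 0.64 in mesothelial-like cells but -0.025 in progenitors and 0.00 in T or NK-like cells, which argues against an immediate early response shared by these classes. Heat shock genes, however, lay lower with disease in mesothelial-like cells at -0.32, in progenitors at -0.56 and in T or NK-like cells at -0.22, so another stress response shared by classes stays open. A response of mesothelial cells alone to digestion, freezing or handling stays open, and so does the disease. A cluster that belongs mostly to 1 library may be that library, and patients cannot be separated within it, so 1 or a few patients may carry either state.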
